A study of Drosophila melanogaster with 2 samples.

How the data were processed

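Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole embryos of a Drosophila melanogaster line that carries ZIPIC (also called CG7928) fused to green fluorescent protein (GFP) at its C terminus. ZIPIC is a zinc-finger DNA-binding protein of the architectural (insulator) class that interacts with CP190. Embryos of both sexes, aged 0 to 24 h, were pooled, chromatin was sheared by sonication with a size range of 200 to 800 (the labels give no unit), and the fusion protein was precipitated with an antibody against GFP, per the labels. The 2 samples form 1 group and are biological replicates, numbered 2 and 3 in the labels. With 1 group there was no comparison between conditions, and the comparisons below are within the peak lists and between the replicates.

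The authors deposited 8 peak lists, 4 on each of 2 genome builds (dm3 and dm6), per the labels and the deposited descriptions of the files. For each build there was a candidate list per replicate and a candidate list from the pooled replicates. A further list of optimal peaks came from an irreproducible discovery rate (IDR) procedure, which assesses how alike peaks rank in replicate data. Candidate lists hold peaks together with weaker background entries. According to the deposited descriptions, both replicates were called against the same control alignment. The peak caller, the aligner and their versions are not given in the sources used here. The authors' signal value is a score per entry, whose scale is not given, and it was used only to rank, filter and describe entries. Each entry also carries a deposited −log10 q-value; it was at its maximum for 74.4% of the optimal dm6 peaks and was therefore not used for ranking. Each entry's summit is a deposited offset in bases. The signal tracks and the control alignment were not analysed here. Read depth per sample was unknown, since the lists hold no read counts, and every binomial interval below is an exact Clopper-Pearson 95% interval that covers counting error over peaks only.

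A check of the lists showed that the 2971 optimal dm6 peaks are the 2971 strongest entries of the pooled list of 30000, and that the 2242 optimal dm3 peaks are likewise the strongest of 28016. The optimal set is thus a cut on pooled signal, and a single peak in it need not be listed in both replicates. The 27029 remaining dm6 candidates served as background, so peaks and background differ in strength by construction. Peaks were placed on Release 6 of the genome, which is the dm6 assembly, and on Ensembl release 115 gene models (BDGP 6.54). Every entry ended within its arm's length in that reference. Coordinates below are on dm6, counted from 1, and none was converted between builds. A promoter peak has its summit within 500 bp of any annotated transcription start site, annotated transposable elements excluded, and other peaks are called distal.

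A peak was found in a replicate when an entry among that replicate's 2971 strongest held its summit. A planned comparison with 100 random sets of background candidates is not reported, since weaker entries of the pooled list can hardly be among a replicate's strongest. Strength in the replicates was compared by Spearman's rho and Pearson's r of log2 signal with 100000 permuted pairings, and the promoter and distal median signals by a permutation test with 100000 resamples. Shares were compared by Fisher's exact test. Arm shares were compared with the shares of background candidates by exact binomial tests. Head-to-head promoters were clusters of protein-coding starts, joined at up to 1000 bp, in which a minus-strand and a plus-strand start of different genes face away from each other. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 6 arms, the 12 motifs or the 25 gene groups.

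A motif was sought among all 6-, 7- and 8-mers in the 100 bp around summits on arms 2L and 2R, against flanks 150 to 250 bp away on each side. The best 8-mer and its neighbours with 1 mismatch were turned into a matrix with 4 further columns on each side, whose score threshold 5% of those flanks passed. The share of summits with a match was then tested on 3L, 3R, X and 4. A further 12 motif strings were fixed before the data were examined, as were the comparisons, the gene groups, the alternatives and the rule for naming peaks, unless stated otherwise. Gene groups were defined by symbol pattern, by list or by annotation class. A gene was bound when an optimal summit lay within 500 bp of one of its starts. The start of another gene could lie nearer, and 1 peak could mark several genes. Of the 22 architectural-protein symbols 20 matched the annotation, as did 16 of 17 segmentation symbols, and the other symbol lists matched completely. The pattern for chorion genes also took Cp190 and Cp110, which are not chorion genes.

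Named peaks and genes were the 20 strongest optimal peaks among the 2971 strongest entries of both replicates, each with the gene whose start is nearest; ZIPIC and every bound architectural-protein and Hox gene; the 4 bound members with the strongest peaks in each gene group past an adjusted p of 0.05; and the 5 strongest distal peaks. Some items that this rule selects are not reported here. The alternatives were the stronger part of the optimal peaks, other windows, other backgrounds, other matching rules, the other build and each replicate's own 2971 strongest entries in place of the optimal set.

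The motif search and the gene group test were tested on simulated data. Exact copies of an arbitrary 8-mer were placed in 20% of simulated summit windows. The planted 8-mer was recovered, and 25.1% of 1860 test windows held a match, the flank rate included. With no motif placed, 5.75% of windows and 5.59% of flanks held one. The copies were identical and the windows lay at random genome positions, so a motif with variable bases or promoter sequence was not covered. A simulated gene list bound at 52% of members was called in all 100 draws, and 0.35% of 2000 tests of unchanged lists were called. That list held 80 genes, drawn independently, so the draws do not cover small lists, weaker effects or neighbouring genes that share a peak. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.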

Results

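Binding of the architectural protein ZIPIC was mapped by ChIP-seq against GFP in whole embryos aged 0 to 24 h, in 2 biological replicates of 1 group. The deposited lists held 30000 candidate entries for each replicate on dm6, and 2971 optimal peaks for the series. The optimal peaks had a median width of 410 bp, and their signal values, the authors' own score, ran from 126 to 7447.

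The first question was where the protein bound most strongly. The strongest peak (3L: 8115749 to 8116326, signal 7447) lay in the intergenic interval between msk, which encodes the nuclear import receptor moleskin, and Arp3, a subunit of the actin-nucleating Arp2/3 complex. Its summit was 86 bp upstream of msk, and it ranked first in replicate 2 (signal 4051) and in replicate 3 (signal 3402). Second was an intergenic peak 31 bp upstream of Sry-delta, a zinc-finger transcription factor gene (3R: 30043056 to 30043586, signal 6212). Next was a peak 121 bp upstream of asRNA:CR44169, within 500 bp of a start of coro, the gene for the actin-binding protein coronin (2R: 6872654 to 6873298, signal 6202); its summit lay in a 3' UTR. These were followed by peaks nearest to sti, the citron kinase of cytokinesis (3L: 12514570 to 12515153, signal 5796), and CG7656 (3L: 15587869 to 15588462, signal 5559).

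All 20 strongest peaks lay at promoters, and each ranked within the first 22 entries of both replicates. The summit was intergenic in 13 of them and in a 5' UTR in 4, and 13 had a start of another gene within 500 bp. Other nearest genes were Reps, SCCRO3, TRAM, CG6254, CG1309, ERR, sowah, PAPLA1, Sfmbt, ATPsynO, Muted, CG2321, Sbat and gry. Among these, ERR encodes a nuclear receptor that controls metabolic genes (3L: 8186377 to 8187153, signal 5269), Sfmbt a Polycomb group protein (2L: 13176515 to 13177261, signal 4907) and ATPsynO a subunit of mitochondrial ATP synthase (3R: 15265344 to 15265835, signal 4685).

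The 2 replicates shared their strongest sites. Of the optimal peaks, 58.5% (1739 of 2971, 95% interval 56.7 to 60.3%) were found among the strongest 2971 entries of both replicates. Compared directly, 58.8% of replicate 2's strongest 2971 entries were found among replicate 3's. With peaks split into 10 deciles of strength, 296 of 297 were found in both in the strongest and 20 of 298 in the weakest, which lies at the rank cut itself. Without that cut, 1 of 297 and 97 of 298 (32.6%) had no entry in replicate 2's whole list. Replicate 3 held 99.2% of the optimal peaks somewhere in its candidate list and replicate 2 held 79.3%, leaving 614 peaks without an entry in replicate 2. Among the 2336 peaks listed in both, signal was correlated between the replicates (Spearman's rho = 0.76, Pearson's r = 0.88 on log2 signal, permutation p = 1e-05 for each, the smallest that 100000 permutations can give). This correlation is across peaks, which are not independent replicates.

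Promoters held most ZIPIC peaks. Of the optimal peaks, 68.4% (2032 of 2971, 95% interval 66.7 to 70.1%) had a summit within 500 bp of a start site, against 23.9% of the weaker candidates (6447 of 27029, 95% interval 23.3 to 24.4%), an odds ratio of 6.91 (95% interval 6.36 to 7.51, Fisher's exact test, with a p too small for the software to represent). The median distance to the nearest start was 168 bp for peaks and 2028 bp for candidates. Coding sequence held 0.505% of the optimal summits and 7.77% of the candidates' summits, 5' UTRs 12.3% and 6.18%, and introns 35.6% and 49.6%. Among the 939 distal peaks, 70.7% of summits were intronic and 24.1% intergenic. In the replicates' own strongest 2971 entries the promoter share was 65.0% ± 14.3 (SD, n = 2), with 54.9% in replicate 2 and 75.2% in replicate 3.

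Promoter peaks were also stronger than distal ones, with median signals of 231.6 and 178.6, a ratio of 1.30 (permutation p = 1e-05, the smallest that the permutations can give). In the decile of peaks with the highest signal 92.6% were at promoters, and in the weakest decile 58.4%.

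**Figure D1:**
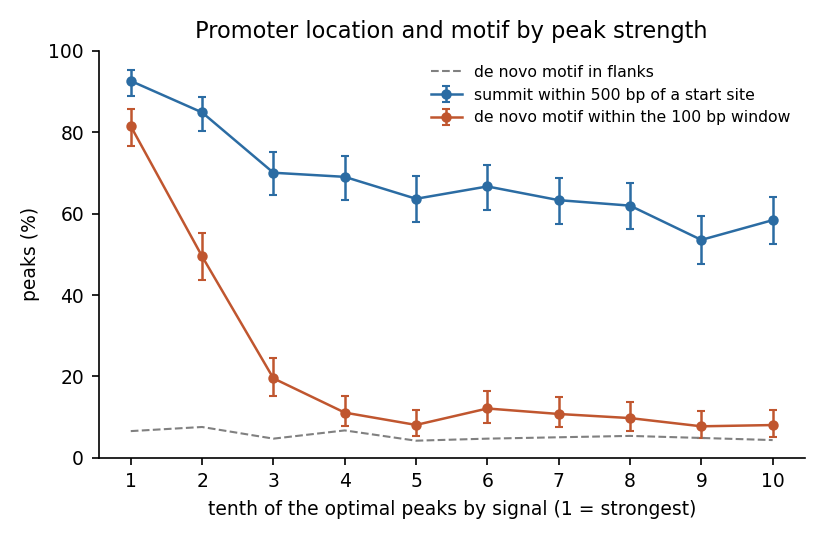
Share of optimal peaks (%, y axis) at promoters (blue) and with the de novo motif in the 100 bp around the summit (red) by decile of peak strength (x axis, 1 = strongest), with exact 95% intervals; the dashed line is the motif share in the same peaks' flanks. Promoter location falls from 92.6% to 58.4% and the motif from 81.5% to 8.05%.

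Head-to-head gene pairs, at which architectural proteins are often described, were bound more often than other promoters. An optimal peak lay at 34.9% of 2453 divergent start clusters (855, 95% interval 32.97 to 36.8%) and at 8.67% of 10673 other clusters (925, 95% interval 8.14 to 9.22%), an odds ratio of 5.64 (95% interval 5.06 to 6.28, Fisher's exact p = 7.66e-210). Pairs bound this way include msk with Arp3, and Dref with RpL13. Divergent clusters hold more starts, and so a wider target, than clusters of 1 gene. Among clusters with exactly 2 genes, a comparison chosen after seeing the data, 34.5% of 2195 divergent and 11.6% of 352 other clusters were bound (odds ratio 3.99, 95% interval 2.84 to 5.74, Fisher's exact p = 3.60e-20), and among starts with a candidate the odds ratio was 3.04 (exact p = 1.76e-77).

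Over the chromosome arms, X held 530 optimal peaks, 17.8% (95% interval 16.5 to 19.3%) of those on the 6 arms, where 13.3% of the candidates lay (1.35 times, exact binomial test, adjusted p = 1.07e-11). This excess depended on the expectation: X makes up 17.6% of the length of the arms, and against length the ratio was 1.01 (exact adjusted p = 0.718), whereas against coding genes it was 1.13 (adjusted p = 0.0127). In replicate 3's own strongest entries, set against its own candidates, the ratio was 1.04 (exact adjusted p = 0.417), and in replicate 2's it was 1.48 (adjusted p = 2.56e-17). Chromosome 4, a small and largely heterochromatic chromosome, held 11 peaks, 0.435 times the share of candidates (exact adjusted p = 0.00380) and 0.368 times that of length (adjusted p = 0.000857), but against its share of coding genes it did not differ (0.645 times, adjusted p = 0.275). Peaks on 2L and 3L were 0.890 and 0.884 times the candidates' share (exact adjusted p = 0.00380 and 0.00159), but against arm length neither arm differed (adjusted p = 0.692 and 0.552).

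The summits held a specific sequence. On 2L and 2R the best 8-mer was CAGCCCTG, whose reverse complement CAGGGCTG is the core that had been listed in advance as a candidate ZIPIC site; it occurred in 7.92% of 1111 summit windows and 0.675% of 2222 flanks. On the other arms the matrix built from it matched 21.7% of summits (404 of 1860, 95% interval 19.9 to 23.7%) and 5.65% of flanks (210 of 3720, 95% interval 4.93 to 6.44%), an odds ratio of 4.64 (95% interval 3.87 to 5.57, Fisher's exact p = 2.72e-68). Over all arms, those used to build the matrix included, it matched 81.5% of summits in the strongest decile, 49.5% in the next, 19.5% in the one after and 7.74 to 12.1% in the remaining deciles, where 4.21 to 6.73% of flanks matched. Of the 20 strongest peaks 14 held it, those at msk, Sry-delta and sti among them, and those at CG1309, ERR and PAPLA1 did not. Searched afresh in each replicate's strongest entries, with the same best 8-mer, the share was 20.4% ± 1.80 (SD, n = 2).

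**Figure D2:**
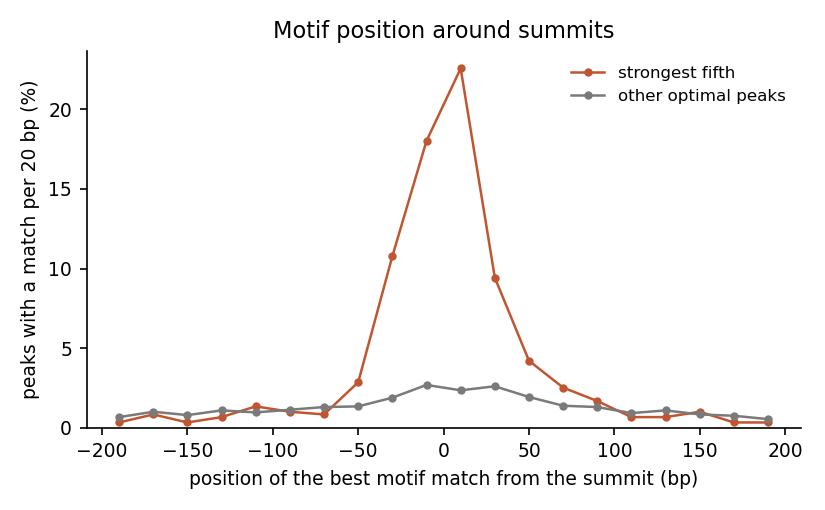
Position of the best match of the de novo motif relative to the summit (x axis, bp) as the percentage of peaks with a match in each 20 bp bin (y axis), for the 594 strongest peaks (red) and the 2377 other optimal peaks (grey). In the strongest peaks the bin just after the summit holds 22.6% and the outermost bins 0.337%.

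Sequences of other promoter and architectural factors differed in how often they occurred at summits. The candidate core CAGGGCTG occurred in 7.51% of summit windows and 0.296% of candidate windows (odds ratio 27.3, exact adjusted p = 6.38e-156), and its shorter form AGGGNTG in 17.0% and 2.72% (odds ratio 7.34, adjusted p = 1.01e-190). CGATA, bound by the insulator protein BEAF-32, occurred in 22.9% and 13.0% (odds ratio 1.98, exact adjusted p = 1.95e-42), and the DNA replication-related element TATCGATA, bound by DREF, in 4.07% and 0.799% (odds ratio 5.27, adjusted p = 7.16e-38). Every TATCGATA also contains CGATA, so the counts of these strings overlap. GGTCACACT, the core promoter element bound by M1BP, occurred in 1.41% and 0.422% (exact adjusted p = 2.82e-09; 0.774% in replicate 2's and 2.63% in replicate 3's own strongest entries), and the TATA box in 7.67% and 4.95% (adjusted p = 4.51e-09). The E-box CACGTG was less frequent in peaks, at 0.808% and 1.27% (exact adjusted p = 0.0477). It missed the threshold in the stronger part of the peaks (exact adjusted p = 0.343), in 50 bp windows (0.175) and in replicate 3's own strongest entries (0.516). It passed as lower in replicate 2's own entries (exact adjusted p = 0.000641), among peaks found in both replicates (0.0306) and against flanks (0.00646). Sites of GAGA factor (exact adjusted p = 0.154), CTCF, Su(Hw) and Zelda (adjusted p = 1 for each) and the initiator (adjusted p = 0.699) did not pass the test. With the peaks' own flanks as background, GAGA sites were less frequent in summits (0.841% and 3.55%, exact adjusted p = 8.76e-16), Su(Hw) sites more frequent (0.606% and 0.219%, adjusted p = 0.00956), and GGTCACACT missed the threshold (adjusted p = 0.0903). In replicate 2's own strongest entries, however, Su(Hw) sites passed as less frequent than in candidates (0.236% and 0.562%, exact adjusted p = 0.0241). When promoter peaks were set against promoter candidates, a comparison chosen after seeing the data, CGATA (28.4% and 19.5%, exact adjusted p = 4.08e-16) and TATCGATA (5.66% and 2.57%, adjusted p = 6.49e-10) still differed, and among distal peaks and candidates CGATA did not (10.8% and 10.99%, adjusted p = 0.952), whereas at promoters GGTCACACT (adjusted p = 0.199) and the E-box (adjusted p = 0.984) no longer did. Among distal peaks and candidates, however, the E-box passed as lower (0.319% and 1.33%, exact adjusted p = 0.0127). The TATA box passed as higher both at promoters (7.48% and 5.62%, exact adjusted p = 0.00669) and among distal entries (8.09% and 4.75%, adjusted p = 7.16e-05). Fisher's exact test was used for each motif, and against candidates matched for GC content the TATA box missed the threshold (adjusted p = 0.0641), as did the E-box (adjusted p = 0.660).

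Ribosomal protein genes were bound far more often than other genes. A peak lay at 61 of 92 cytoplasmic ribosomal protein genes (66.3%, against 18.0% of other protein-coding genes; odds ratio 8.94, 95% interval 5.69 to 14.3, exact adjusted p = 1.24e-22). Strong peaks among them were at RpL3 (3R: 11221405 to 11221942, signal 2205, summit 193 bp from the start) and RpL34a (3R: 26059173 to 26059603, signal 1989, 168 bp), both with intergenic summits. Mitochondrial ribosomal protein genes followed with 28 of 73 bound (38.4%, odds ratio 2.79, exact adjusted p = 0.000222), led by mRpL47, mRpL54, mRpL41 and mRpL12 with signals of 2530, 1598, 1517 and 1513. Translation factors had 17 of 52 bound (32.7%, exact adjusted p = 0.0358), among them eEF1gamma (signal 2329), eIF4A (2125), eIF6 (1018) and eIF3a (736). Respiratory chain genes had 25 of 80 bound (31.3%, exact adjusted p = 0.0191), led by ATPsynO (signal 4685), COX5A (2174), ND-19 (1843) and ATPsynG (1454). At RpL3, RpL34a, mRpL47, eIF6 and eIF3a the start of another gene lay nearer to the summit. Of the 61 bound cytoplasmic ribosomal protein genes, 36 had their strongest peak found in both replicates. The strongest peak held the de novo motif at 19 of the 61. Whether peaks without the motif mark ZIPIC or unspecific recovery of promoters was not tested. No precipitation from untagged embryos was used here. The strongest peak was found in both replicates for 19 of 28 bound mitochondrial ribosomal protein genes. For bound translation factors it was 9 of 17, and for bound respiratory chain genes 8 of 25. In the replicates' own strongest entries, 52.2% ± 13.8 (SD, n = 2) of cytoplasmic and 35.6% ± 5.81 of mitochondrial ribosomal protein genes were bound. In the stronger part of the peaks the translation factors (15.4% against 10.8%, exact adjusted p = 0.605) and the respiratory chain genes (12.5% against 10.8%, adjusted p = 1) missed the threshold, as they did among genes with a candidate (adjusted p = 0.137 and 0.272). Neither the translation factors nor the respiratory chain genes passed in replicate 2's entries alone (17.3% and 12.5% bound, Fisher's exact adjusted p = 1 for each). Among genes with any candidate at a start, only the cytoplasmic ribosomal protein genes still passed as bound more often (exact adjusted p = 4.02e-11), and mitochondrial ribosomal protein genes did not (49.1% against 36.1%, adjusted p = 0.162).

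Odorant and gustatory receptor, cytochrome P450 and cuticle genes were nearly free of peaks. None of 119 odorant and gustatory receptor genes was bound (exact adjusted p = 8.52e-10), 1 of 85 cytochrome P450 genes (Cyp6u1, signal 285, adjusted p = 8.90e-06) and 1 of 92 cuticle genes (Lcp9, signal 289, adjusted p = 1.96e-06). Of these genes, 96 receptor, 59 P450 and 76 cuticle genes had no candidate at all, and among genes with a candidate the receptors (exact adjusted p = 0.000484) and P450 genes (adjusted p = 0.00225) still passed as lower while the cuticle genes did not (6.25% against 36.2%, adjusted p = 0.0853). The summits at Cyp6u1 and Lcp9 lay nearer to starts of other genes, Ufsp1 (15 bp) and CG3594 (60 bp). Separately, 4 histone genes were bound, namely His2Av (signal 1362), His4r (966), His3.3B (129) and His3.3A (127), which encode variant or replacement histones. The peaks at His3.3B and His3.3A had no entry in replicate 2's list, and at His2Av and His4r the start of another gene lay nearer to the summit. The other 111 histone genes had no candidate at all, so the low share is not evidence of less binding; why they had none was not tested.

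**Figure D3:**
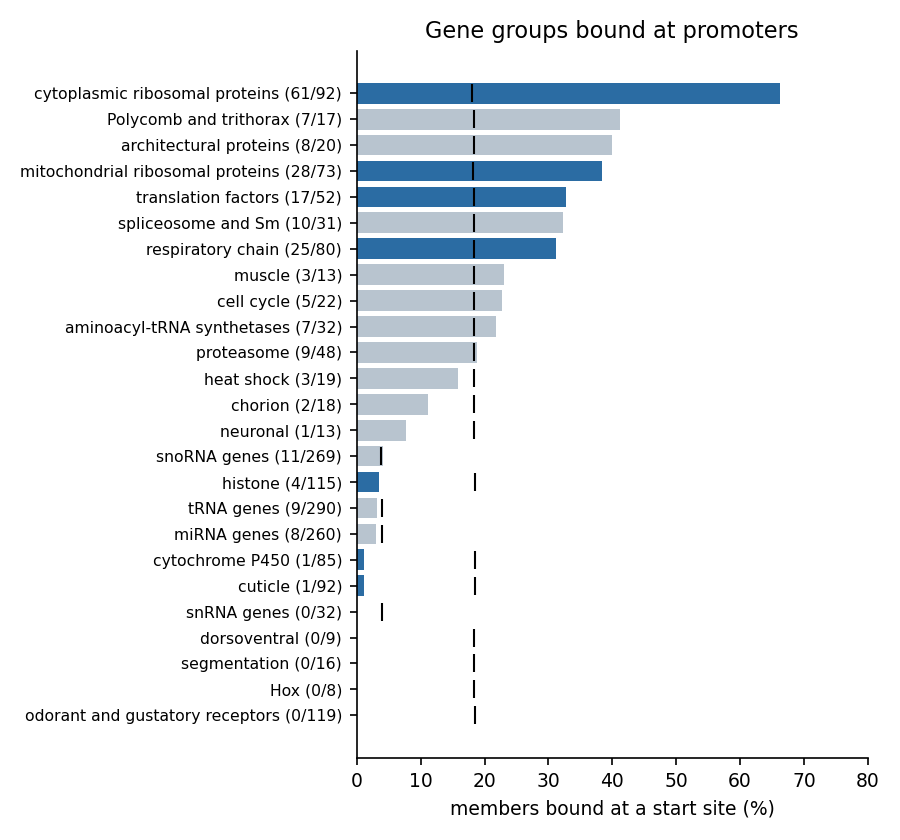
Percentage of each gene group's members bound at a start site (x axis) for the 25 groups (y axis, bound and total members in parentheses); blue bars passed an adjusted p of 0.05 and grey bars did not (most histone genes have no candidate), and black ticks mark the share among other genes of the same class. Cytoplasmic ribosomal proteins stand highest at 66.3%, and several developmental and sensory groups are at 0.

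Architectural proteins' own genes were bound at 8 of 20 (40.0%, odds ratio 2.97, exact adjusted p = 0.0550), and Polycomb and trithorax genes at 7 of 17 (41.2%, odds ratio 3.12, adjusted p = 0.0610), neither past the threshold. In replicate 3's entries alone both passed (45% and 52.9%, Fisher's exact adjusted p = 0.0260 and 0.00842), in replicate 2's neither did (30% and 23.5%, adjusted p = 0.164 and 0.768), and the Polycomb and trithorax genes also passed within 1000 bp of starts (47.1%, adjusted p = 0.0386). The bound architectural genes were Chro (signal 1004), Cp190, which encodes ZIPIC's partner (3R: 15275220 to 15275437, signal 541, intergenic summit 97 bp from the start), Dref (382), pzg (317), Trl (261), M1BP (247), Cap-H2 (147) and BEAF-32 (129). The peaks at Trl, Cap-H2 and BEAF-32 had no entry in replicate 2's list. At M1BP, Cap-H2 and pzg the start of another gene lay nearer to the summit. ZIPIC itself (3R: 30035240 to 30036870, minus strand) had no optimal peak at its start; the nearest summit was 6440 bp from the gene's upstream end, in the peak at Sry-delta. No Hox gene (0 of 8, exact adjusted p = 0.679), segmentation gene (0 of 16, adjusted p = 0.125) or dorsoventral gene (0 of 9, adjusted p = 0.679) was bound, numbers too small to pass the test. Spliceosome and Sm genes (10 of 31, exact adjusted p = 0.125), proteasome genes (9 of 48, adjusted p = 1), aminoacyl-tRNA synthetases (7 of 32), heat shock genes (3 of 19), cell cycle genes (5 of 22), muscle genes (3 of 13), neuronal genes (1 of 13) and the chorion pattern (2 of 18, namely Cp190 and Cp110) did not differ detectably from other genes (adjusted p from 0.769 to 1 for the last 6). Nor did tRNA (9 of 290), snoRNA (11 of 269), snRNA (0 of 32) and miRNA genes (8 of 260), with adjusted p from 0.769 to 0.945 by Fisher's exact test. Within 1000 bp of starts, however, snoRNA genes passed as bound more often (16.0% against 6.99%, exact adjusted p = 7.81e-06).

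Strong distal peaks were few. The strongest lay in an intron, 690 bp downstream of the nearest start of the zinc-finger gene zf30C (2L: 9758760 to 9759287, signal 2252, rank 101), and the next in a 5' UTR 510 bp downstream of a start of CG12054 (3R: 31220443 to 31221383, signal 2051). The others were in introns nearest to CG11050 (2L: 6612522 to 6612890, signal 1937, 1029 bp) and CG32295 (3L: 2531356 to 2531757, signal 1789, 4575 bp), and in an intergenic region 4296 bp upstream of Nlg3, a neuroligin gene (3R: 7643540 to 7643931, signal 1895). Of these 5 peaks 4 held the de novo motif.

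The same experiment on the older build gave fewer peaks. The optimal list held 2242 peaks on dm3 and 2971 on dm6, a ratio of 1.33, all of them on the 6 arms on either build. The lowest signal accepted was 150.2 on dm3 and 126.0 on dm6. Of the dm3 optimal peaks, 60.1% were found in both replicates, against 58.5% on dm6.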

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

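On dm3, candidate entries lay on contigs outside the 6 arms. They stayed in the replicate lists used for the share of dm3 peaks found in both replicates, and no comparison examined them separately. Replicate 2's list had 1282 such entries and replicate 3's had 30, each of 30000. Most of those in replicate 2 were on the heterochromatic contigs 2RHet (421), 3LHet (351) and 3RHet (272), and 181 were on the unplaced contig U. None of the 2242 optimal dm3 peaks lay there. On dm6, replicate 2 had 2 entries outside the 6 arms and replicate 3 had 0. With 1 list per replicate and no control list used here, the difference was not tested, and no biological explanation was tested.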

How the results depend on the processing

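The share of optimal peaks found in both replicates was 58.5% and moved with the set of peaks and with the rule. It was 85.8% for the stronger part of the peaks, matched to as many leading replicate entries as all peaks were. That cut was laxer relative to the number of peaks, so the 85.8% is not a like-for-like share. Over all peaks the share was 78.6% with the replicates' whole lists and 73.4% with the strongest 2 times as many entries. It was 60.4% when any overlap counted and 55.5% when summits had to lie within 100 bp. The X ratio of 1.35 fell to 1.01 with arm length and to 1.13 with coding genes as expectation and ranged from 1.04 to 1.48 without either replicate. The divergent odds ratio of 5.64 fell to 3.04 among starts with a candidate. The number of gene groups bound more often was 4, and it was 2 with the stronger part of the peaks, 2 with peaks found in both replicates (an alternative chosen after seeing the data), 1 among genes with a candidate, and 2 to 6 without either replicate. All optimal peaks lie on the 6 arms, so leaving out other sequences could not move the ratio between builds, and taking the stronger part of both lists keeps that ratio by construction.

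The direction of the difference from background changed for the motifs and groups given here. Of these, the E-box CACGTG, respiratory chain genes and histone genes had passed the threshold in the analysis as reported. In the stronger part of the peaks these were AGRKGGC (CTCF, 4.58%), TGCATANTTT (Su(Hw), 0.471%), chorion (11.1%), cell cycle (9.09%) and muscle (7.69%). Among peaks found in both replicates they were TGCATANTTT (0.403%), CAGGTAG (Zelda, 0.403%), aminoacyl-tRNA synthetases (9.38%), respiratory chain (10%), chorion (11.1%), cell cycle (9.09%) and muscle (7.69%). In windows of 50 bp they were AGRKGGC (2.05%) and TGCATANTTT (0.168%). In windows of 200 bp they were GAGAGAG (3.06%), TGCATANTTT (1.14%), CAGGTAG (0.707%) and CACGTG (2.69%). With flanks as background they were AGRKGGC (4.07%), CAGGTAG (0.438%) and TCAGTY (8.82%), and with GC-matched candidates AGRKGGC (4.07%). At promoters, again chosen after seeing the data, they were AGRKGGC (4.23%), TGCATANTTT (0.344%) and CAGGTAG (0.394%).

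Within 250 bp of starts the direction changed for heat shock (15.8%), tRNA (2.07%) and snoRNA genes (1.49%), and within 1000 bp for proteasome (18.8%) and heat shock genes (26.3%). Also within 1000 bp, snoRNA genes (16.0%, Fisher's exact adjusted p = 7.81e-06) and Polycomb and trithorax genes (47.1%, adjusted p = 0.0386) passed as higher, and respiratory chain genes missed the threshold (adjusted p = 0.0620). Among genes with a candidate it changed for proteasome (32.1%), aminoacyl-tRNA synthetases (31.8%), heat shock (42.9%), histone (100%), chorion (100%) and cell cycle (26.3%). Without either replicate the ranges were 4.04 to 4.11% for AGRKGGC, 0.236 to 0.404% for TGCATANTTT, 0.370 to 0.471% for CAGGTAG, 12.5 to 28.1% for aminoacyl-tRNA synthetases, 12.5 to 38.8% for respiratory chain, 13.6 to 27.3% for cell cycle, 2.97 to 4.83% for snoRNA, 15.4% in both for muscle and 2.41 to 4.48% for tRNA genes. With flanks as background GAGAGAG (0.841% against 3.55%, Fisher's exact adjusted p = 8.76e-16) passed as lower, TGCATANTTT passed as higher (0.606% against 0.219%, adjusted p = 0.00956) and GGTCACACT missed the threshold (adjusted p = 0.0903). In the opposite direction, TGCATANTTT without replicate 3 passed the threshold as lower (0.236% against 0.562%, Fisher's exact adjusted p = 0.0241). The cause of these changes was not tested.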

Other observations

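All tests in this part were chosen after the peak lists had been examined, though the outcomes of 4 of them (missing candidates outside the optimal set, the looser threshold, the wider window and the BEAF-32 strings) had not been seen when their predictions were written. Gene groups were also counted separately for peaks with and without the de novo motif. Peaks with the motif marked 20 of 92 cytoplasmic ribosomal protein genes (21.7%, against 5.57% of other genes, exact adjusted p = 4.12e-06) and peaks without it 43 of 92 (46.7%, against 13.3%, adjusted p = 2.98e-13). Polycomb and trithorax genes were bound at 7 of 17 by peaks without the motif (41.2%, against 13.5%, exact adjusted p = 0.0181) and at 0 of 17 by peaks with it, where 5.69% of other genes were, so that 0 is no departure. These 7 were ph-p, brm, E(z), skd, Su(z)12, trx and Pc. The Polycomb group gene Sfmbt was not on the list of 17, and its peak (signal 4907) held the motif. Architectural protein genes were bound at 7 of 20 by peaks without the motif (35%, exact adjusted p = 0.0403) and at 1, pzg, by a peak with it (5%, against 5.68%). The same groups missed the threshold over all peaks (exact adjusted p = 0.0610 and 0.0550), the difference between the kinds of peak was not tested, and only 3 of the 7 Polycomb and trithorax genes and 5 of the 8 architectural genes had their strongest peak in both replicates' leading entries. Among proteasome genes, which did not differ as a group, Prosalpha3 had a peak of signal 2643, Prosalpha4 of 2088 and Prosbeta1 of 2055. Among heat shock genes, Hsp83 had a peak of signal 3140. These genes were singled out after their values were seen.

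The 614 optimal peaks absent from replicate 2's list were at promoters in 83.1% of cases, against 64.6% of the 2357 that were found. Pooled peak strength alone cannot account for this: within deciles of pooled signal, absent peaks exceeded found ones by 27.7 percentage points of promoter share, where 10000 permutations within deciles gave -7.88 to 8.76. At equal pooled signal, a peak absent from replicate 2 can draw more on replicate 3. Replicate 3's own strongest entries were 75.2% promoter and replicate 2's 54.9%. Strength within a replicate was not tested, so the comparison says nothing about it. GC content remains open: absent peaks had 0.776 percentage points more GC (permutation p = 0.018, permuted values -1.41 to 1.2), and no test linked a difference of that size to absence. A lower yield of promoter entries throughout replicate 2's list remains a candidate explanation, since its whole list was 17.9% promoter against 35.4% in replicate 3. Among weaker candidates that replicate 3 listed, 69.2% of promoter ones and 54.0% of distal ones were missing from replicate 2 (odds ratio 1.91, 95% interval 1.77 to 2.06). That comparison starts from replicate 3's list, so it cannot tell a deficit in replicate 2 from an excess in replicate 3. Absent peaks also held the motif less often (12.9% against 24.1% of found peaks), a share not adjusted for peak strength. Whether the difference between the lists comes from the chromatin, the precipitation or the sequencing was not tested, nor was any biological explanation.

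The motif share fell from 81.5% to 8.05% over the deciles of peak strength. A score threshold too strict for weak sites is argued against: at a threshold that 20% of flanks pass, the excess of summits over flanks in the weaker part of the peaks (22.1% against 19.7%) was 0.105 of that in the stronger part (44.0% against 20.4%; bootstrap 95% interval of the ratio -0.00738 to 0.222). The matrix was built from sites with at most 1 mismatch to the best 8-mer, so this covers sites like those and not more divergent ones. At the threshold and window used elsewhere the ratio was 0.172 (0.114 to 0.236), so loosening did not raise it. Imprecise summits do not account for it alone, since in windows of 400 bp, against windows 1000 bp away, the ratio was 0.235 (0.157 to 0.320), somewhat above 0.172 with overlapping intervals, so a small contribution is not excluded. Whether signal at promoters that lack the motif explains the fall remains open. Optimal peaks without the motif were at promoters in 63.2% of cases (1467 of 2323), an odds ratio of 5.47 over the other candidates (95% interval 5.002 to 5.99), but a value above 1 was implied by the promoter share of all peaks. The odds ratio was 7.08 in the stronger and 4.58 in the weaker part of the peaks, and as it is taken among peaks that already lack the motif, it does not measure how much such promoters contribute to the fall. No biological explanation was tested.

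A hypothesis that promoter peaks without the motif are those with BEAF-32 strings was tested and came out the opposite way. CGATA occurred in 22.8% of 1467 promoter peaks without the motif and in 43.2% of 565 with it (odds ratio 0.388, 95% interval 0.314 to 0.480, Fisher's exact p = 4.58e-19). Peaks with the motif are stronger, and within deciles of strength the odds ratio was 0.518. The longer string TATCGATA occurred in 3.82% and 10.4%.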
